A study of Mus musculus with 19 samples.

How the data were processed

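RNA sequencing libraries from 19 mouse samples were used, all with a group in the labels. Per the labels' protocols, cells were sorted by GFP, each isolate came from 1 mouse and counted as a separate sample, isolates with poor RNA were left out, and some libraries were sequenced again. The submitters' processing notes name the mm10 genome, TopHat2, Partek and DESeq2, without versions. The deposited table held 1 signal value per gene and library for 18639 gene symbols. Each was a read count divided by a library factor, per the file headers and the values, and is called normalized reads here. The deposited table also held p-values, adjusted p-values and fold changes of the authors for 2 comparisons. Those were used only to count calls.

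Whole reads were recovered from the steps between low values. Of the values under 10000 reads 100.0% were whole within 0.1 read, and 99.89% of all values above 0 were. The factors recovered this way differed by at most 0.091% from DESeq2 size factors recomputed from the reads. Of the symbols, 18472 were found in the reference annotation (GENCODE M21 for mm10), which gave the gene positions. No replicate pair agreed within sampling noise (chi-square per degree of freedom 50.5 to 920.3), so each library counted as 1 replicate. Libraries held 20.6 to 71.6 M reads (M, mega). A gene with no reads could have had up to 3 reads per library, which is 1.38 to 5.33 normalized reads. Such floors, and the 95% intervals of ratios between single libraries, cover counting error only, since the reads carry no molecular identifiers.

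The samples' groups, the tests, the gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. The design had planned for counts or for normalized values. The table held normalized values, so limma with a mean-variance trend and robust variance was the main test. It was fitted to log2(value + 1) of the 14 sorted whole-cochlea libraries, with 4 group means and 1 shared estimate of spread. Genes needed a value of at least 1 in at least 2 libraries, which left 18441. The 6 contrasts of the report were taken, each with Benjamini-Hochberg adjustment at 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. Where a group had no reads, a lower bound was taken against 3 reads per library. Such bounds were rounded to 3 digits and can lie slightly above the exact bound.

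Fixed gene lists of cell types and pathways were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Of 53 lists 51 were tested, without the mitochondrially encoded and X inactivation lists. For each main comparison the named genes were the 8 with the largest log2 difference each way among called genes with a mean of at least 20 in the higher group, groups that did not overlap, and symbols that were not predicted, clone, Xist or Y-linked names. To these were added the 3 members with the smallest adjusted p from lists called by camera, given in the text for the lists described, and 6 genes as sort checks. The interaction named 4 genes each way by adjusted p. Members of near-identical families, such as Bglap and Bglap2, Hba-a1 and Hba-a2, Ccl3 and Ccl4 and the ribosomal proteins, can share reads, and their separate values are uncertain. Some genes that met these rules are not reported here. The lists described in the text were picked after their results were seen. The auditory nerve, lateral wall and unsorted libraries were single and had no test. List medians there were set against 10000 random lists matched on expression.

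The other settings fixed in advance were quantile normalization, a common total, library quality weights, no trend, no filter or a filter of 10, pseudocounts of 0.1 and 10, fits of only the groups compared, pooling of the auditory nerve and lateral wall libraries, and leaving out each library. Alternatives chosen after the data were seen were edgeR, DESeq2 and voom on the recovered reads, thinning to 20 M reads, fits within depth class, the substructure libraries as the only young macrophages, and a mean of at least 100. edgeR's quasi-likelihood test on the recovered reads called 6924, 5073, 3089, 3861, 3 and 1653 genes in the 6 comparisons, in the order of the report. In the table that the authors deposited, 5798 genes had an adjusted p under 0.05 between old and young macrophages (3997 higher, 1801 lower), and 6937 between young macrophages and nonmacrophages (2284 higher, 4653 lower).

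The limma step was tested on simulated counts with 200 changed genes. With the spread of old nonmacrophages in every group, it recovered 34.3% of 2-fold and 100.0% of 4-fold and 8-fold changes between old and young macrophages, with 14 false calls among 18501 genes. With the mean spread of the groups in every group it recovered 0% of 2-fold, 4-fold and 8-fold changes in that comparison, with 0 false calls among 18492 genes. With each group's own spread it recovered 3.0%, 35.8% and 48.5% of 2-fold, 4-fold and 8-fold changes, with 2466 false calls among 18479 genes. For the sort comparison over both ages that simulation gave 1000 false calls among 18490 genes, and for age in nonmacrophages 0 among 18486 by limma without weights, with 19 by quality weights. There it recovered 0%, 1.5% and 6.1% of 2-fold, 4-fold and 8-fold changes. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.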

Results

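Gene expression was measured by RNA sequencing in cells sorted from the mouse cochlea, the hearing organ of the inner ear. The mice carried green fluorescent protein (GFP) in place of 1 copy of Cx3cr1, a chemokine receptor gene active in macrophages, so GFP-positive cells were collected as macrophages and GFP-negative cells as nonmacrophages. Young mice were 1.5 months old and old mice 12 to 14 months old. Whole cochleae gave 4 old macrophage, 2 young macrophage, 4 old nonmacrophage and 4 young nonmacrophage libraries. The young auditory nerve and the young lateral wall each gave 1 macrophage and 1 nonmacrophage library, and 1 young cochlea was left unsorted.

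The old libraries held 50.6 to 71.6 M reads in genes (M, mega). The young whole-cochlea libraries held 24.9 to 35.1 M reads, except nonmacrophage replicate 14 with 60.2 M reads, so depth and age nearly coincided. The old macrophage libraries had reads in 16750 to 17282 genes, and the young macrophage replicates 9 and 15 in only 11652 and 13532. The unsorted young library reached 17468 genes with 20.6 M reads. With every library thinned to 20 M reads, young macrophage replicate 9 kept 11509 genes and the old macrophage libraries 16497 to 16838.

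**Figure D1:**
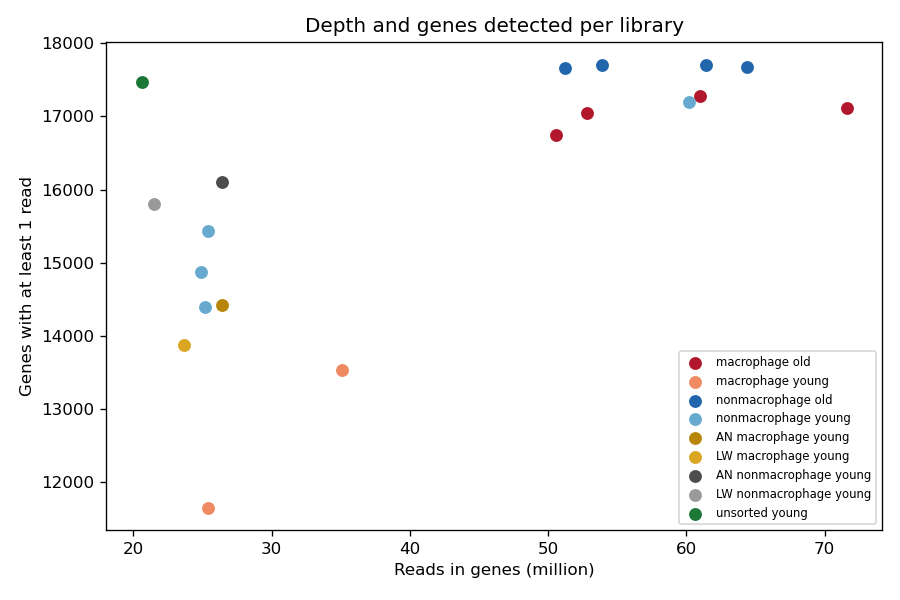
Reads in genes (horizontal axis, in M reads) against the number of genes with at least 1 read (vertical axis), 1 point per library, coloured by group (AN, auditory nerve; LW, lateral wall). The 2 young whole-cochlea macrophage libraries lie lowest, at 11652 and 13532 genes.

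The first comparison asked which genes distinguished the GFP-positive from the GFP-negative cells over both ages. The genes that mark macrophages were far higher in the GFP-positive sort. Cx3cr1 itself (mm10, chromosome 9, 119901616 to 120069879) stood at 8733 ± 1617 normalized reads in old macrophages and 56.2 ± 34.7 in old nonmacrophages (SD, n = 4 each). In the young cochlea it stood at 9201 and 22528 in the 2 macrophage libraries and at 2.6 ± 1.22 in nonmacrophages (SD, n = 4). Csf1r, the receptor for the growth factor CSF1 on which macrophages depend, rose by 8.95 on the log2 scale (SE 0.48, limma adjusted p = 4.8e-08). The log2 differences of the other sort checks were 8.93 for C1qa, 8.86 for Adgre1, 7.23 for Aif1 and 5.59 for Ptprc, all past the threshold.

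All 19 measured members of the macrophage core list rose, with a median log2 difference of 8.31, and the same 19 passed when adjusted over the list alone. Among them Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 7.43 (SE 0.25) and the complement gene C1qc by 8.79 (SE 0.29). In the list of resident perivascular-type macrophages 13 of 14 genes rose (13 when adjusted over the list alone), among them the mannose receptor gene Mrc1 (log2 difference 9.84), the scavenger receptor gene Stab1 (5.30) and Cd209f (9.59). In the microglia-type list 9 of 11 genes rose and 1 fell, the same numbers as when adjusted over the list alone. Siglech rose by 8.96 and P2ry13 by 9.91. These 3 lists were higher than other genes by camera (adjusted p = 7e-23, 2.2e-13 and 6.8e-09). Each stayed so with an estimated correlation (adjusted p = 0.0043, 0.0043 and 0.0019).

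Chemokine genes were higher in macrophages, with 14 of 22 measured members up, 4 down and 15 up when adjusted over the list alone. Ccl12, Ccl3 and Ccl4, which encode chemokines that attract monocytes and other leukocytes, showed log2 differences of 11.36, 10.03 and 10.06. Ccl4 averaged 17807 ± 2075 normalized reads in old macrophages and 44.1 ± 14.9 in old nonmacrophages (SD, n = 4 each). In the list of Fc receptors and phagocytosis 16 of 22 genes rose and 1 fell, with 16 and 2 when adjusted over the list alone. They included Fcgr3 (7.73) and Trem2 (8.82), a lipid-sensing receptor of microglia. Both lists were called by camera (adjusted p = 1.1e-06 and 6e-11) and with an estimated correlation (adjusted p = 0.015 and 0.039). Of the MHC class II list, which presents antigen, 9 of 13 genes rose (9 when adjusted over the list alone), including Ctss (8.82), H2-DMa (3.21) and H2-DMb1 (2.01). That list had an adjusted p = 3.2e-07 by camera and an adjusted p = 0.1 with an estimated correlation. The remaining genes with the highest log2 differences were Il1a (10.34), Gpr84 (10.14), Lilra5 (9.98) and Ms4a6d (9.89).

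The GFP-negative sort was richer in matrix and glial genes. Of 30 collagen and matrix genes 28 were lower in macrophages, and 28 when adjusted over the list alone (camera adjusted p = 2.7e-11, adjusted p = 0.00097 with an estimated correlation). Col1a1, a chain of type I collagen, fell by 7.37, the fibrillin gene Fbn1 by 6.22 and the proteoglycan gene Dcn by 4.12. Of 16 Schwann cell and glia genes 15 fell, and 16 when adjusted over the list alone (camera adjusted p = 2.2e-08, adjusted p = 0.051 with an estimated correlation). Mbp, which encodes myelin basic protein, stood at 3087500 ± 461470 normalized reads in old nonmacrophages and 111700 ± 75086 in old macrophages (SD, n = 4 each). The genes with the most negative log2 differences included bone genes (Ibsp, -9.25; Bglap, -9.03; Bglap2, -8.34) and myelin-associated genes (Ermn, -8.72; Ncmap, -8.35; Mog, -7.99), with Klk6 (-9.15) and Crhbp (-8.07). Bglap and Bglap2 are near-identical neighbours, and their separate values are uncertain. All 14 endothelial genes and 11 of 12 pericyte and smooth muscle genes also fell (14 and 12 when adjusted over the list alone). These lists had camera adjusted p = 0.00053 and 0.0026, and adjusted p = 0.18 and 0.17 with an estimated correlation. With library quality weights only 2 endothelial and 1 pericyte and smooth muscle genes were called lower, against 23 collagen and matrix and 10 Schwann cell and glia genes. In the young cochlea alone the main test called 4 endothelial and 4 pericyte and smooth muscle genes lower (9 and 4 when adjusted over the list alone).

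Neuronal genes were higher in the GFP-positive cells of the whole cochlea. Of 16 spiral ganglion neuron genes 12 rose and 2 fell, with 13 rising when adjusted over the list alone. The camera adjusted p was 2.3e-08, against an adjusted p = 0.063 with an estimated correlation. Snap25, a component of the synaptic vesicle fusion machinery (mm10, chromosome 2, 136713453 to 136782428), stood at 148160 ± 7239 normalized reads in old macrophages and 4628 ± 1304 in old nonmacrophages (SD, n = 4 each). The neurofilament genes Nefl and Nefm rose by 4.51 (SE 0.35) and 4.01 (SE 0.26). In the unsorted library Snap25 stood at 104016, near its level in macrophages. In the auditory nerve and the lateral wall, with 1 library of each sort, the list was mixed or lower. In the auditory nerve 7 of 16 genes were higher in the macrophage library, among them Snap25 (18339 against 13534), Nefl and Nefm, and 9 were lower, and the list's mean log2 value was 8.75 against 10.02. In the lateral wall no gene was higher in the macrophage library and 13 were lower, with a mean of 1.87 against 5.17. Pooling these libraries with the whole cochlea ended the calls of Snap25, Nefl and Nefm.

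In all, 7244 of 18441 genes passed limma's adjusted p of 0.05, 2512 higher and 4732 lower in macrophages. The median log2 difference of all genes was -0.50, and quantile normalization, which removed that shift, gave 3567 higher and 3766 lower. Data simulated with each group's own spread and 200 genes changed with the sort gave 1000 false calls among the unchanged genes. Library quality weights, which gave each of the 2 young macrophage libraries a weight of 0.07, called 2624 genes (681 higher, 1943 lower).

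**Figure D2:**
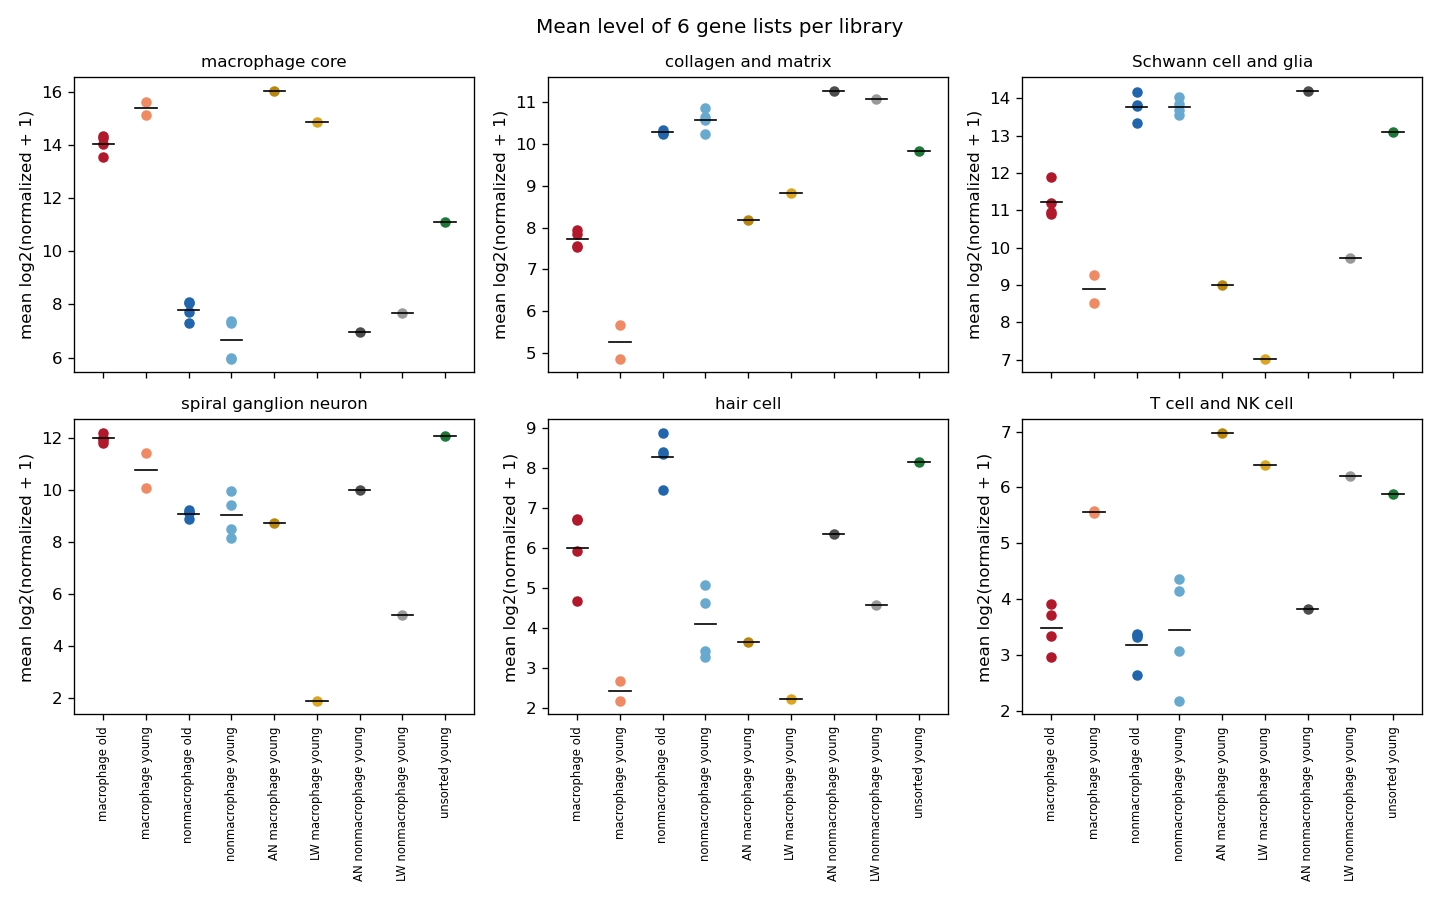
Mean log2(normalized reads + 1) of 6 gene lists (vertical axes), 1 point per library, with libraries grouped by sort, age and tissue (horizontal axis) and a line at each group mean. The macrophage core list separates the sorts, and the collagen and Schwann cell lists run the other way.

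The same sort difference was taken within each age. In the old cochlea 18 of 19 macrophage core genes and 12 of 16 spiral ganglion neuron genes were higher in macrophages, and 19 of 30 collagen and matrix genes were lower (18, 12 and 24 when adjusted over the list alone). Those 3 lists were called by camera and with an estimated correlation (adjusted p = 0.0044, 0.039 and 0.00075 with an estimated correlation). In the young cochlea 18 of 19 core genes and 11 of 16 neuron genes were higher, and 25 of 30 collagen and matrix genes were lower (19, 11 and 26 when adjusted over the list alone). With an estimated correlation the adjusted p = 0.0043, 0.12 and 0.0013. Csf1r rose by 7.57 (SE 0.60) in the old and by 10.33 (SE 0.74) in the young cochlea, Snap25 by 5.04 (SE 0.46) and 3.94 (SE 0.57), and Col1a1 had log2 differences of -4.61 (SE 0.64) and -10.12 (SE 0.79). In the old cochlea, with 4 libraries in each group, 3431 genes passed, 1705 higher and 1726 lower in macrophages. Fitting only the 8 old libraries gave 10654 genes (4546 higher, 6108 lower), and 3420 of the 3431 were called in the same direction. In the young cochlea, with 2 macrophage libraries, 5814 genes passed, 1693 higher and 4121 lower. Only 1426 passed when the 6 young libraries were fitted alone, and 589 among the young libraries under 40 M reads. Quantile normalization split the young calls into 2361 higher and 2797 lower.

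The next comparison asked how cochlear macrophages differed between old and young mice. Part of the MHC class I and lysosome lists was lower in old macrophages. Of 16 MHC class I genes 7 fell and none rose. The immunoproteasome genes Psmb8 and Psmb9, which cut peptides for antigen presentation, fell by 2.70 (SE 0.43) for Psmb8 and fell by 2.47 (SE 0.37) for Psmb9, and the class I heavy chain gene H2-D1 fell by 1.52 (SE 0.29). Psmb8 stood at 2803 ± 620 in the 4 old libraries (SD) and at 21546 and 14800 in the 2 young ones. In the lysosome list 11 of 30 genes fell and 2 rose. The counts of both lists stayed at those numbers when adjusted over the list alone. Ctsh, a cathepsin, fell by 2.29, Hexa by 1.44 and Lgmn by 1.43. The camera adjusted p was 3.6e-05 for MHC class I and 9.2e-07 for the lysosome, against an adjusted p = 0.18 and 0.45 with an estimated correlation. Of 13 MHC class II genes only H2-DMa was called, lower in old (camera adjusted p = 0.046, adjusted p = 0.59 with an estimated correlation). Of 19 inflammatory cytokine genes 6 rose and 2 fell, with a camera adjusted p = 0.95 and an adjusted p = 0.98 with an estimated correlation, and quantile normalization gave 2 and 2. Both lists had the same counts when adjusted over the list alone.

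The macrophage core list, whose genes rose with the sort, was also lower than other genes in old macrophages, with a median log2 difference of -1.53. H2-D1, Hexa and Lgmn fell by no more than that, and Psmb8, Psmb9 and Ctsh by more. Whether the MHC class I and lysosome lists fell beyond macrophage genes in general was not tested. The core list's mean log2 value was 13.54 to 14.34 in the 4 old and 15.15 to 15.62 in the 2 young libraries. Of its 19 genes 2 fell, C1qc and Tyrobp, named after their values were seen, and 1 when adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.27 with an estimated correlation). Quantile normalization ended both calls. Part of the resident and microglia-type lists was lower as well. In the microglia-type list 5 of 11 genes fell, and 7 fell and 1 rose when adjusted over the list alone (camera adjusted p = 7.9e-05, adjusted p = 0.046 with an estimated correlation). Cst3, a protease inhibitor, fell by 2.36 (SE 0.39), the matrix protein gene Sparc by 2.15 (SE 0.46) and Tmem119 by 1.38 (SE 0.31). In the resident perivascular-type list 3 of 14 fell, namely Cbr2, Folr2 (-2.91) and Ccl24 (-2.79), and 5 when adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.16 with an estimated correlation). Of 84 ribosomal protein genes 21 fell, and 18 when adjusted over the list alone (camera adjusted p = 7.9e-19, adjusted p = 0.48 with an estimated correlation). Ribosomal genes that fell included Rpsa (-1.73) and Rpl7 (-1.77). Of 14 T cell and NK cell genes 5 fell, the same number as when adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.15 with an estimated correlation). Gzma and Gzmb, which encode granzymes of cytotoxic lymphocytes, averaged 7.16 ± 14.3 and 2.44 ± 4.88 normalized reads in old macrophages (SD, n = 4 each). In the 2 young libraries Gzma stood at 4269 and 418, and Gzmb at 2061 and 274. Nkg7 (-6.68), Ctsw (-5.95), Gimap5 (-5.64) and Cd2 (-5.06) ran in the same direction, as did Gpihbp1 (-6.44), Trem3 (-5.71) and Skint3 (-5.69). Markers of vessels moved the same way in these libraries, with 7 of 14 endothelial genes and 5 of 12 pericyte and smooth muscle genes lower, the same numbers as when adjusted over the list alone (camera adjusted p = 1e-04 and 0.00035, adjusted p = 0.27 each with an estimated correlation). Quantile normalization ended the calls of Cbr2, Tmem119 and Lgmn, and scaling to a common total that of Folr2.

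The genes named here for the largest rises in old macrophages had no reads in the 2 young whole-cochlea libraries. Pkia, an inhibitor of protein kinase A (mm10, chromosome 3, 7366669 to 7445366), averaged 2350 ± 539 in old macrophages (SD, n = 4), at least 543-fold above the level that 3 reads per young library would give. It stood at 289 and 470 in the young auditory nerve and lateral wall macrophage libraries. By the same measure Sez6 was at least 414-fold higher, B3galt5 344-fold, Miat 322-fold, Firre 289-fold, Sphkap 270-fold and Grm7 247-fold. Sez6 and Sphkap also had no reads in the auditory nerve and lateral wall macrophage libraries. Markers of other cell types moved with age in the same libraries. Of 16 spiral ganglion neuron genes 5 rose, of 16 Schwann cell and glia genes 9 rose, and of 30 collagen and matrix genes 11 rose and 2 fell (5, 10, and 12 with 2 when adjusted over the list alone). Of 14 hair cell genes 6 rose, among them Otof and Tmc1, and of 14 supporting cell genes 6 rose, with none lower in either list (10 and 7 higher when adjusted over the list alone). None of these 5 lists was called by camera (adjusted p = 0.68, 0.07, 0.073, 0.074 and 0.062). By fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, the neuron list was not called (adjusted p = 0.06) and the other 4 were (adjusted p = 0.00046, 1.3e-06, 0.0011 and 5.1e-05).

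Limma called 5468 genes, 4441 higher and 1027 lower in old macrophages, around a median log2 difference of 0.88 over all genes. Quantile normalization split the calls into 2292 higher and 2277 lower. Of the 4441 genes called higher, 36.4% had no reads in both young whole-cochlea libraries and 61.3% had none in at least 1 of them. In every old library 46.3% of the 4441 lay above both young auditory nerve and lateral wall macrophage libraries. Of the 1027 called lower, 68.8% lay below both in every old library. The 2 young libraries had a common dispersion of 2.36 against 0.15 for the 4 old ones. Data were simulated with 1 such dispersion per group and 200 genes changed with age. They gave 2466 false calls among the unchanged genes, of which 78.9% were higher in old. With library quality weights limma called 362 genes, all higher (2589 higher and 111 lower at an unadjusted p under 0.05), and none of the lower genes named above passed, whereas edgeR on the recovered reads called 2976 higher and 885 lower, DESeq2 3964 and 1913, and voom with quality weights 0 and 9. Every old macrophage library was deep and both young ones shallow, so no comparison within a depth class could be made. With every library thinned to 20 M reads 5206 genes were called, 4127 higher and 1079 lower.

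**Figure D3:**
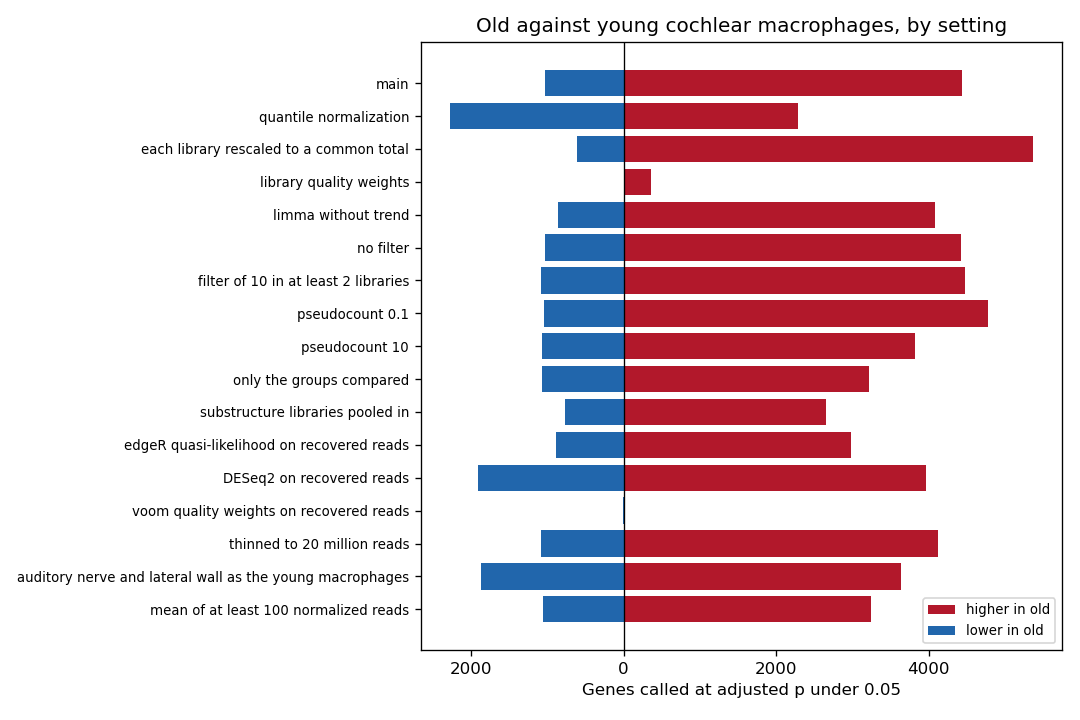
Number of genes called at an adjusted p under 0.05 (horizontal axis) between old and young cochlear macrophages under each setting (vertical axis), with genes higher in old to the right of 0 and lower in old to the left. The main setting gave 4441 higher and 1027 lower, and quality weights gave 362 higher and 0 lower.

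The same age difference was then taken in the nonmacrophages. Hair cell genes were higher in the old GFP-negative libraries, with 7 of 14 called, none lower and 9 called when adjusted over the list alone. The list median was a log2 difference of 5.33 (camera adjusted p = 2e-06, adjusted p = 0.18 with an estimated correlation). By the interaction contrast, which compares this age difference with that in macrophages, the list median was -0.03 (camera adjusted p = 0.13), with -2.75 after quantile normalization and 0.06 after scaling to a common total. Otof, which encodes the otoferlin protein of hair cell synapses (mm10, chromosome 5, 30367062 to 30461932), stood at 1368 ± 929 in old and 34.0 ± 39.5 in young nonmacrophages (SD, n = 4 each). Tmc1, part of the mechanotransduction channel, stood at 548 ± 226 and 10.85 ± 11.1, and Loxhd1 at 121 ± 49.3 and 0.94 ± 1.87 (SD, n = 4 each). Pou4f3, a hair cell transcription factor gene, was at least 23.4-fold higher in old than the level of 3 reads per young library. The unsorted young library held 1864 normalized reads of Otof, 783 of Tmc1, 125 of Loxhd1 and 159 of Pou4f3.

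Genes of cilia also had large rises. Spag6l and Ttc29, which encode ciliary proteins, were at least 37.7-fold and 40.6-fold higher in old nonmacrophages. Tekt1, a tubulin-associated filament gene, stood at 216 ± 104 against 1.22 ± 2.45 (SD, n = 4 each), and at 234 in the unsorted young library. Cyp2g1 was at least 67.2-fold and Skor1 at least 38.8-fold higher, and Cdkl4 and Slc6a14 rose by 7.64 and 7.07. The changes of the 8 genes named for their falls were smaller. The potassium channel genes Kcnj10 and Kcnj13 fell by 2.28 and 2.63, Ifitm5 by 3.62, Sparc by 2.01, Arhgdib by 1.40, Cd38 by 1.38, Ssr2 by 1.31 and Car14 by 1.29. Markers of macrophages also moved in these GFP-negative libraries. Of 19 macrophage core genes only Cx3cr1 rose, by 3.85 (SE 0.54), and 4 when adjusted over the list alone, with a list median of 1.44 (camera adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation). Quantile normalization ended that call, at a list median of 0.51. The list's mean log2 value was 7.29 to 8.09 in the old and 5.95 to 7.38 in the young libraries. The globin genes Hba-a1, Hba-a2 and Hbb-bs had log2 differences of -3.79, -3.96 and -3.78 and did not pass (adjusted p = 0.0827, 0.0824 and 0.0824). Limma called 0 of 26 oxidative phosphorylation genes, also when adjusted over the list alone, with 14 lower at an unadjusted p under 0.05, and the list was lower than other genes by camera (adjusted p = 6.5e-09, adjusted p = 0.4 with an estimated correlation). Limma called 0 of 84 ribosomal protein genes, also when adjusted over the list alone, with 44 lower at an unadjusted p under 0.05. Their median was -0.93 (camera adjusted p = 8.7e-23, adjusted p = 0.44 with an estimated correlation), and their interaction median was -0.19 (0.04 after scaling to a common total). Of 17 immediate early genes, which respond quickly to stimulation and handling of cells, limma called 0, with 8 higher at an unadjusted p under 0.05 and 4 higher when adjusted over the list alone. Their median was 1.16 (camera adjusted p = 0.013, adjusted p = 0.79 with an estimated correlation). The erythroid list, which holds the globin genes, had 0 of 8 called by limma, 5 lower at an unadjusted p under 0.05 and 5 lower when adjusted over the list alone, a camera adjusted p = 0.00021 and an adjusted p = 0.31 with an estimated correlation.

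Limma called 318 genes, 303 higher and 15 lower, around a median log2 difference of 0.39. Quantile normalization gave 76 higher and 13 lower and ended the calls of Otof, Slc6a14, Kcnj13, Arhgdib, Cd38 and Car14, while edgeR called none of the named genes. Other tests gave counts from 3 genes (edgeR on the recovered reads) to 1670 (DESeq2, 525 higher and 1145 lower), and leaving out young replicate 14 gave 3562 (2256 higher, 1306 lower). The deep libraries alone, 4 old against young replicate 14, gave 135 genes, 46 of them among the 318 in the same direction. In that fit the lone young library was assumed to vary like the old groups.

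**Figure D4:**
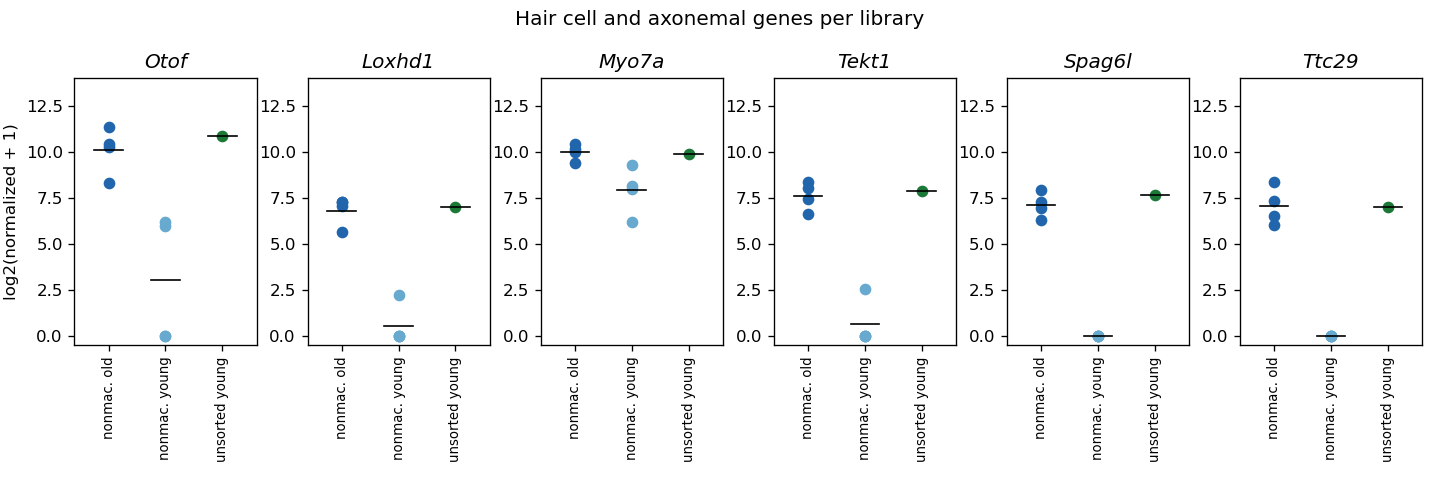
Log2(normalized reads + 1) (vertical axes) of 3 hair cell genes and 3 ciliary genes in old nonmacrophages (4 libraries), young nonmacrophages (4 libraries) and the unsorted young library, 1 point per library with a line at each group mean. Otof and Tekt1 in the unsorted library lie within the range of the old libraries.

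The log2 difference between old and young was higher in macrophages than in nonmacrophages for 1288 genes and lower for 176, by the interaction contrast (1464 in all). The median over all genes was 0.46, and quantile normalization gave 415 and 223. Pkia (10.71, SE 0.56), Vmo1 (9.69), Osbpl5 (8.94) and Ppm1l (8.34) had the smallest adjusted p above 0, and Vrtn (-6.11), Esp18 (-4.64), Hfe (-2.39) and Rnase4 (-2.20) below 0. Vrtn and Esp18 had no reads in any whole-cochlea macrophage or young nonmacrophage library, and stood at 68.7 ± 11.4 and 24.9 ± 8.42 in old nonmacrophages (SD, n = 4 each). In the microglia-type list 3 of 11 genes were lower and in the collagen and matrix list 8 of 30 were higher by this contrast, with 4 and 10 when adjusted over the list alone (camera adjusted p = 0.00025 and 0.00053, adjusted p = 0.041 each with an estimated correlation). The macrophage core list, with medians of -1.53 for age in macrophages and 1.44 in nonmacrophages, had an interaction median of -2.76, with 2 of 19 genes lower, Cx3cr1 and C1qc, named after their values were seen, and 8 when adjusted over the list alone (camera adjusted p = 6.8e-08, adjusted p = 0.09 with an estimated correlation). Quantile normalization ended both calls. Library quality weights gave 148 genes, and voom with quality weights on the recovered reads 0, with 1053 at an unadjusted p under 0.05, against 1653 by edgeR and 2973 by DESeq2.

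The auditory nerve and lateral wall macrophages were compared as single libraries, with no replicate check. The 2 libraries differed by at least 8-fold for 1898 of 12862 genes with at least 50 normalized reads in one of them. Neuronal genes led in the auditory nerve. Nefl was at least 1620-fold, Crtac1 at least 737-fold and Nefm at least 577-fold above the level of 3 reads in the lateral wall, and Snap25 stood at 18339 against 6.1. Slc2a5, a fructose transporter gene, stood at 4893 normalized reads against no reads in the lateral wall. In the lateral wall Lrp2 stood at 64907 against 5.0, which was 3 reads, so the log2 ratio of auditory nerve to lateral wall had a 95% counting interval of -15.95 to -12.13. Kcne1, a potassium channel subunit of strial marginal cells, stood at 19788 against 1.7, which was 1 read, with an interval of -18.85 to -11.07. Fgd5 was at least 636-fold and Tacr3 at least 561-fold higher there. Of the genes just named, only Slc2a5 had no reads in the nonmacrophage library of the same tissue. In auditory nerve nonmacrophages Nefl stood at 6352, Snap25 at 13534, Nefm at 992 and Crtac1 at 547. In lateral wall nonmacrophages Lrp2 stood at 12945, Kcne1 at 8299, Fgd5 at 1375 and Tacr3 at 303. The ratios therefore need not be differences between the macrophages themselves. All 11 microglia-type genes were higher in the auditory nerve library, with a median log2 ratio of 1.92 against -0.15 to 0.81 for the central 95% of random lists matched on expression. General macrophage genes were higher there as well, with 17 of 19 core genes (median log2 ratio 1.26, random lists -0.01 to 0.66) and 12 of 14 resident perivascular-type genes (2.17, random lists -0.19 to 0.53). All 11 marginal cell genes were higher in the lateral wall library, with a median log2 ratio of -7.00. In the nonmacrophage libraries the median log2 ratio was 6.62 for 16 myelin genes and -3.72 for 12 melanocyte and intermediate cell genes.

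The unsorted library was placed by the genes called for the sort over both ages whose young libraries differed in the same direction, 2424 of the 2512 higher and 4673 of the 4732 lower in macrophages. It lay near the nonmacrophages for those lower in macrophages. On the log2 scale the median gene of 4673 lay 4.3% of the way from young nonmacrophages to young macrophages. For the 2424 higher in macrophages the median was 50.1%, with quartiles of 4.5% and 98.5%. These are shares of a log2 distance, not of cells or RNA.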

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

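The tests on free RNA, on the spread between the young libraries, on random lists matched to the hair cell list, on hair cells in the unsorted library and on axonemal genes were chosen only after the results they address had been seen.

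Samples far from the rest of their group were found in 24 of 233 gene-by-group checks, where chance gives about 1 in 20. Young nonmacrophage replicate 14 had 60.2 M reads, far above the other 3. In the same library Gpr84 stood at 11.2, Slc6a14 at 28.3 and Nefm at 460.5 normalized reads, apart from the rest. Cdkl4 at 1.1 and Ccl24 and Loxhd1 at 3.7 there, and Tekt1 at 4.9 in replicate 6, met the same rule but lay below the 5.33 that 3 reads would give in replicate 2, so no difference was detectable at this depth. Old macrophage replicate 17 stood apart for Ccl4 (14705.1), Ncmap (1058.4), Gzma (28.7), Gzmb (9.8) and Trem2 (4609.7), and replicate 12 for Bglap (3.2). Old nonmacrophage replicate 11 stood apart for Il1a (6.9), Kcnj10 (1229.8), H2-DMa (760.5), Ptprc (383.3) and Aif1 (214.7), and replicate 19 for Sdhb (7091.5). Among young nonmacrophages, replicate 2 stood apart for Kcnj13 (86847.4) and Vmo1 (50452.8), replicate 5 for Nefl (4881.3) and Adgre1 (98.1), and replicate 6 for Fbn1 (1470.1).

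The age difference itself differed between macrophages and nonmacrophages for 1464 genes by the interaction contrast. The interaction was above 0 for Pkia (10.71), Sez6 (10.35), Sphkap (9.94), Grm7 (9.84), Vmo1 (9.69), Osbpl5 (8.94), Ppm1l (8.34), Miat (6.70) and Ifitm5 (5.43), on the log2 scale. It was below 0 for Skint3 (-6.90), Cd2 (-6.21), Vrtn (-6.11), Ccl24 (-5.12), Folr2 (-4.65), Esp18 (-4.64), Gimap5 (-4.12), Psmb9 (-2.76), Hfe (-2.39), Psmb8 (-2.29), Rnase4 (-2.20), Tmem119 (-1.62) and Hexa (-1.33). The median was -1.22 for the microglia-type list and 2.45 for the collagen and matrix list.

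More genes were higher than lower in old cochlear macrophages (4441 and 1027). Depth alone was argued against, since 91.8% of the genes called higher stayed called after thinning to 20 M reads. Few distinct transcripts in the 2 young libraries stay open: the median difference of those genes against the auditory nerve and lateral wall libraries was 28.6% of that against the young whole-cochlea libraries, but genes called against replicate 9 alone had a median of 5.79 against it and 0.89 against replicate 15, so the choice of genes can by itself give such a drop. The larger spread of the young libraries also cannot be told apart from a real change for part of the genes. Data simulated with it gave 2466 calls among genes simulated without a change, 45.1% of the observed number of calls. Age stays open as untested by these, because both young libraries carry the same limits.

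Neuronal genes were higher in the GFP-positive sort of the whole cochlea, whereas in the single auditory nerve libraries 7 of 16 spiral ganglion neuron genes and 9 of 20 genes of a second neuronal list were higher in the macrophage library, and 0 and 3 in the lateral wall. A candidate explanation is that neurons were collected with the GFP-positive cells: in the second list, written before its test, 80% (16 of 20) were higher in that sort at both ages, and 15 were called higher (16 in the old libraries alone, 9 in the young alone and 6 with the auditory nerve and lateral wall libraries pooled in), with Eno2 at 22858 ± 4732 in old macrophages and 1520 ± 194 in old nonmacrophages (SD, n = 4 each). The second list shares no gene with the spiral ganglion neuron list, and how many of its genes macrophages express was not tested. Both lists hold neuronal genes, so the second could hardly go another way than the first. Its rise would also follow from free neuronal RNA or from neuronal transcripts within macrophages, so it does not tell these apart. In the single unsorted young library the spiral ganglion neuron list had a mean log2 value of 12.08. That compares with 10.10 and 11.44 in young macrophages and 8.16 to 9.98 in young nonmacrophages. Whether the sort difference was a gain in the GFP-positive sort or a low level in the GFP-negative sort was not tested. Free RNA in the sort stays open: the 20 most abundant genes of the GFP-negative cells had a median log2 difference of -1.59, but they were picked for their abundance in those cells, which favours a negative value, and RNA from lysed neurons need not share their profile. A GFP gate should remove cells that do not express Cx3cr1, but glial transcripts were still present after it. The mean log2 value of the Schwann cell and glia list was 10.91 to 11.90 in old macrophages and 13.35 to 14.16 in old nonmacrophages. The gate is therefore no argument against neurons in the sort, and neuronal transcripts within macrophages stay open.

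Hair cell genes were higher in old nonmacrophages, at a median log2 difference of 5.33, and 6 of 14 were called higher in old macrophages too. A loss of transcripts in the young libraries that struck genes of like level alike was argued against, since that median lay at percentile 100 of random lists matched on the old level, whose central 95% ran from -0.25 to 1.12, and each of the 4 young libraries lay above its own random range (medians of 3.65 to 5.88, with upper limits of 0.28 to 1.87). A loss shared by hair cell genes, which random lists do not model, is not excluded by this. Loss of hair cells from the young GFP-negative sorts is a candidate explanation. The unsorted young library lay 0.50 above the old nonmacrophages at the list median, and 12 of 14 genes lay at or above the lowest old library. Slc26a5 and Ocm did not, at 0 and 68.8 against 92.2 to 345.7 and 468 to 1074.5 in old nonmacrophages. In young nonmacrophages they stood at 0 to 11.2 and 42.7 to 171.3. These genes do not go with such a loss, and the unsorted young sample is 1 library. Tissue with motile-type cilia in the old preparations stays open, as 10 of 31 axonemal genes were called higher (one-sided Fisher's exact test p = 4.04e-11). That list was written after some such genes had been seen to be called, and it leaves those out. Fisher's test counts genes that can move together as independent, so its p-value does not measure agreement between libraries. The unsorted young library lay at -0.15 for the 10 called genes, so these values do not separate such tissue from a loss during sorting. Age stays open as untested, since the unsorted library has no old counterpart.

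Other splits of the same libraries were tried for 3 counts. For the sort over both ages 1 of 100 splits within age gave as many genes, the real one with 7244, and the highest other gave 3225. For the old cochlea 1 of 35 splits did (3431, highest other 0), and for age in nonmacrophages 1 of 35 (318, highest other 7). This makes chance unlikely for the 3 counts but does not exclude it, since 1 of 35 is the smallest share that 35 splits can give. For the old cochlea every other split mixed the sorts, and for age in nonmacrophages every other split mixed the ages. Such mixing by itself widens the spread within groups and lowers the other counts. The same holds for splits of the sort over both ages that mixed the sorts. For age in nonmacrophages the splits do not separate age from depth, and edgeR called only 3 genes.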

How the results depend on the processing

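The alternatives with edgeR, DESeq2 or voom on the recovered reads, thinning, depth classes, a mean of at least 100 and the auditory nerve and lateral wall libraries as the young macrophages were chosen after seeing the data. No paired analysis was made, because no replicate number is shared to pair the libraries by. Unshared numbers do not show that the macrophage and nonmacrophage libraries came from different mice. The sort tests treated all libraries as independent. No named gene reversed its direction, but the balance of higher and lower calls turned with voom for the sort over both ages and in the young cochlea, for age in both sorts, and with DESeq2 for age in nonmacrophages. In the old cochlea (1705 higher, 1726 lower) it was near even and turned with several settings, among them edgeR (1819 and 1270). By count, a common total, no trend, no filter, pseudocounts of 0.1 and 10, a 2-fold minimum and thinning left all 6 counts within 1.5 times, as did a filter of 10. Where counts moved further, the cause was not tested. For the sort over both ages, quality weights gave 2624 genes and voom with such weights 2505 (1598 higher, 907 lower, against 2512 and 4732). In the young cochlea these gave 575 (33 higher, 542 lower) and 373 (340 higher, 33 lower, against 1693 and 4121), the compared groups alone 1426 and libraries under 40 M reads 589. In the old cochlea they gave 11167 and 11043, the compared groups alone 10654, libraries over 40 M reads 10670 and pooling of the substructure libraries 1877. For age in macrophages quality weights gave 362, pooling 3421 and voom 9 (0 higher, 9 lower; 1263 and 741 at an unadjusted p under 0.05). With the substructure libraries as the young macrophages 5512 genes passed, 2206 of the 5468 in the same direction and 198 in the other. For age in nonmacrophages quantile normalization gave 89, quality weights 190, the compared groups alone 175, libraries over 40 M reads 135, a mean of at least 100 gave 4, edgeR 3 (1131 higher and 2181 lower at an unadjusted p under 0.05), DESeq2 1670 (525 higher, 1145 lower) and voom 549 (152 higher, 397 lower, against 303 and 15). For the interaction quantile normalization gave 638, quality weights 148, pooling 358, DESeq2 2973 and voom 0 (1053 at an unadjusted p under 0.05), with edgeR at 1653.

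Of the lists, an estimated correlation left 7 of 32 for the sort, 1 of 18 for age in macrophages, 0 of 17 for age in nonmacrophages and 2 of 19 for the interaction. In the order just given fry called 37, 22, 3 and 18 lists in 1 direction and 49, 44, 24 and 34 in either. For age in macrophages pooling gave 29 lists and the substructure libraries as the young macrophages 28. At a level of 200 the auditory nerve and lateral wall differed 8-fold for 997 genes. The unsorted library lay at 68.9% of the log2 distance for the 717 genes higher at 8-fold among those that placed it. For the 1986 lower it lay at 2.9%.

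Where leaving out a library left 1 young macrophage library, it was assumed to vary like the other groups. Leaving out 1 library gave 6280 to 9408 genes for the sort over both ages, 5028 to 7984 in the young and 2369 to 5477 in the old cochlea. It gave 4206 to 8490 for age in macrophages, 167 to 3562 for age in nonmacrophages and 1116 to 5369 for the interaction. Young macrophage replicate 15 decided the highest count for age in macrophages and the interaction (2503 without replicate 9), and young nonmacrophage replicate 14 that for age in nonmacrophages (1076 and 1063 without macrophage replicates 9 and 15, 169 without old replicate 10, 11 or 18). The old count was 5477 and 5471 without young macrophage replicates 9 and 15. Lists ranged from 24 to 35, 6 to 23, 13 to 19 and 4 to 22 in the order above, with 6 for age in macrophages and 4 for the interaction without young macrophage replicate 15. Of the named genes 31 of 43 for the sort passed under every setting, 0 of 32 for age in macrophages (28 lost with quality weights), 0 of 19 for age in nonmacrophages (19 lost with edgeR) and 0 of 8 for the interaction. In the sorted young whole-cochlea libraries the depth of 24.9 to 35.1 M reads, replicate 14 aside, limits low genes to a floor of 3.39 to 5.33 normalized reads.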

Other observations

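The gene groups given here were picked after their values were seen. Among sort differences not described in the report, oxidative phosphorylation genes were higher in macrophages than in nonmacrophages, with 18 of 26 called and none lower (19 when adjusted over the list alone). The camera adjusted p was 3.6e-09, against an adjusted p = 0.19 with an estimated correlation. Inflammatory cytokine genes had 10 of 19 higher and none lower, and 10 when adjusted over the list alone (camera adjusted p = 5.1e-05, adjusted p = 0.12 with an estimated correlation). Of 16 fibroblast and fibrocyte genes 13 were lower in macrophages, and 13 when adjusted over the list alone, with a median log2 difference of -2.89 (camera adjusted p = 2.2e-07, adjusted p = 0.015 with an estimated correlation).

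In the auditory nerve macrophage library 16 of 17 immediate early genes lay above the lateral wall library, with a median log2 ratio of 1.53 against -0.09 to 0.59 for the central 95% of random lists matched on expression. Of 25 cell cycle genes 24 were higher in the lateral wall macrophage library (median log2 ratio -1.15, random lists -0.25 to 0.38). The nonmacrophage libraries of the same tissues went the same way, with 13 of 17 immediate early genes higher in the auditory nerve (median log2 ratio 0.85, random lists -0.32 to 0.45) and 24 of 25 cell cycle genes higher in the lateral wall (-1.92, random lists -0.37 to 0.46). These are single libraries with no replicate check.

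In 7 of 19 libraries both Xist, expressed from an X chromosome in female cells, and the Y-linked gene Ddx3y stood at 100 or more normalized reads. In old macrophage replicates 12 and 17 Xist stood at 480.6 and 1094.3 and Ddx3y at 1751.4 and 1223.6. In old nonmacrophage replicates 11 and 18 Xist stood at 411.6 and 588.9 and Ddx3y at 1319.3 and 2145.4. The other 3 were the auditory nerve macrophage, auditory nerve nonmacrophage and lateral wall nonmacrophage libraries, with Xist at 692.2, 100.7 and 168.2 and Ddx3y at 2309.6, 2149.6 and 1691.4. The labels give each library as cells of a single mouse, and no test of the source of both signals was made. Old macrophage replicate 1 and old nonmacrophage replicate 10 held Ddx3y at 3616.7 and 3676.8, with Xist at 0 and 16.6. Old macrophage replicate 7 and old nonmacrophage replicate 19 held Xist at 707.4 and 575.5, with Ddx3y at 2.7 and 2.2. The old sorts thus held like sets of sex signals, and whether they came from the same mice was not tested.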
